A study of Arabidopsis thaliana with 4 samples.

How the data were processed

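The samples were chromatin immunoprecipitations (ChIP) from whole roots of Arabidopsis thaliana seedlings grown for 6 days on MS medium. Per the labels, an anti-GFP antibody was used on roots of upb1-1 plants carrying UPB1 fused to GFP under its own promoter (UPB1-GFP) and on roots of untagged wild type plants. UPB1 (UPBEAT1, AT2G47270 in the TAIR10.1 names used here) is a basic helix-loop-helix (bHLH) transcription factor. Per the labels' protocols, the precipitated DNA was amplified with 22 PCR cycles, and 2 µg was labelled with Cy3 or Cy5. Both precipitates were hybridised together on 2-colour Agilent arrays. The series' design text names a dye swap for 2 biological replicates, which gives 4 arrays. Array 1 of replicate 1 and array 2 of replicate 2 carried UPB1-GFP DNA in Cy3, and the other arrays carried it in Cy5.

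The spot intensities were measured with Agilent Feature Extraction 9.5.1.1 under a CGH protocol, per the file headers. The processed signals had the background subtracted, spatial and multiplicative trends removed and the dyes normalized linearly, and dim spots carried a surrogate value, per the file headers. The deposited log10 ratio of each array is Cy5 over Cy3. The deposited value table holds log10 ratios too, and each of its columns equalled the log10 ratio of its array once the sign was turned for array 1 of each replicate (largest difference 4.99e-06). All its column medians were 0, and its centring beyond that of the scanner software is not given in the sources used here. By the dyes of the labels, its columns run UPB1-GFP over wild type in replicate 1 and wild type over UPB1-GFP in replicate 2. The deposited flags, 0 or 1 per spot, mark outliers, saturation and signals well above background. The genome build was left empty in the file headers, and the labels name none.

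Each array held 237976 genomic spots and 5528 control spots. The genomic spots came from 237575 probes of up to 60 bp with a median spacing of 159 bp, and 400 probes were spotted more than once. Control spots and spots with an outlier flag were left out and saturated spots were kept. After 4145 probes with no unflagged spot on some array were left out, 233430 probes remained, of which 195122 were well above background in both channels on all 4 arrays. The precision was limited by the number of arrays. In most named results that include other probes, the number of probes well above background is given.

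From the processed signals, the log2 ratio of UPB1-GFP over wild type was taken on each array, averaged over the spots of a probe and centred on the array's median. No loess or quantile step was used for these ratios, but the fold bounds of the dim probes came from channel values after loess and Aquantile. The arrays of a dye swap were averaged first, so that n = 2. Averaging cancels a dye effect only where it is equally large on both arrays. In dim control spots of the kind NC2, the median log2 ratios were -0.22 and 0.65 in replicate 1. They were 0.24 and -0.45 in replicate 2, so part of a dye effect may remain in dim probes. Both arrays of a replicate were scanned on 1 date, so replicate and scan date coincide. Each array held both genotypes, and the values per replicate are therefore the values within a scan date. The ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. Tests were run per probe and per interval of 1200 bp with at least 3 probes (39220 intervals). Regions were found without a p-value. A window mean was taken over the probes within 250 bp of each probe (at least 3), and a region was a run of at least 3 probes, merged within 500 bp, whose window means lay at least 3 robust SDs (scaled median absolute deviations) above the median in both replicates. The same rule mirrored to low values, and to high values in 1 replicate with low values in the other, served as background. E-box sequences (CANNTG and CACGTG, the usual sites of bHLH proteins) were counted in the probe sequences of regions and of 100 control stretches per region with as many probes and a similar length, whose window means at both ends lay within 1 robust SD of the median, with a two-sided Fisher's exact test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

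The design fixed before the data were examined called for promoters, 1000 bp upstream to 200 bp downstream of gene starts, for tests of gene lists and for named genes. The TAIR10.1 gene table used here could not be joined to the probes, since the build of the array is not given and probe positions ran past the extent of that table. Intervals of the same total length in the coordinates of the array took the place of promoters, gene names were not assigned to positions, and the tests of gene lists were not run. Items named were the 10 highest intervals past the threshold with the same sign on all 4 arrays, the 5 lowest by the same rule (with none past it, the 5 lowest with the same sign on all 4 arrays), and up to 10 regions. All probes past the threshold are given too, and so are a few regions from a lower threshold, chosen after their values were seen.

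The tests were tried on simulated data. Among 233430 simulated probes, 7 of 100 raised by 1 on the log2 scale and 96 of 100 raised by 2 were recovered, and 4 unchanged probes were called. These probes were drawn from a normal distribution with the same SD for all probes and both replicates. For simulated intervals the SD was set by the number of probes, again alike in both replicates. Recovery in the real data, where the replicates differ in spread, may be lower. Among 39220 simulated intervals, 93 of 100 raised by 1 and 100 of 100 raised by 2 were recovered, and 21 unchanged intervals were called. With a variance trend over the number of probes per interval, the same simulated intervals gave 93, 100 and 10, and this fit was added as an alternative. The region rule recovered 19 of 49 places of 5 probes raised by 1 and 48 of 49 raised by 2. For this the real ratios were shuffled over the probes, which removes the likeness of neighbouring probes. Window means then vary less, so recovery in the unshuffled data may be lower. Alternatives were normexp (offset 50) on the mean signals, loess, centring on the mode, the value table, bright probes only, other thresholds and windows, a robust variance trend over the mean ratio, and leaving out each array or replicate. Added after the data were seen were other interval lengths, the value table with its deposited sign, removal of GC and brightness trends, and all 4 arrays with the replicate as a random block. The variance trend over the number of probes, and the trend over the mean ratio and the robust fit taken singly, were also added then.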

Results

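The data were 4 arrays of 2 biological replicates, each replicate hybridised with the dyes in both orientations. Every array set anti-GFP ChIP DNA from roots of UPB1-GFP plants against anti-GFP ChIP DNA from untagged wild type roots. The untagged wild type was therefore the background of every ratio. The question was where UPB1, a transcription factor that the series ties to the control of reactive oxygen species in the root, was bound in the genome. Between 88.4% and 95.5% of genomic spots were well above background in either channel, apart from the Cy5 channel of array 2 of replicate 1, where 86.2% were. The median background brightness was 33 to 35.5 in Cy3 and 70 to 75 in Cy5, against median spot brightness of 181.0 to 193.6 in Cy3 and 186 to 263 in Cy5. All coordinates below are those of the array design, whose genome build is not given in the sources used here. No gene, exon or promoter was therefore assigned to a position.

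UPB1-GFP DNA was most enriched over wild type in a region of chromosome 2 from 19419278 to 19420395. Its mean log2 ratio of UPB1-GFP over wild type was 2.05 ± 0.25 (SD, n = 2), a 4.14-fold enrichment. These signs follow the dyes of the labels, and the deposited value table runs the opposite way in replicate 2. The region held 11 probes, and all 11 were well above background in both channels on all 4 arrays. Replicate 1 gave 2.23 and replicate 2 gave 1.87, and the single arrays ranged from 1.87 to 2.30. Its highest probe, 19420169 to 19420228, with the sequence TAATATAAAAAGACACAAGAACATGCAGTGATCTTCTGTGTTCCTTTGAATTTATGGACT, had a log2 ratio of 2.43 ± 0.13 (SD, n = 2; limma adjusted p = 0.0251).

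The probes of this place formed a stretch of 2766 bp with 12 probes, because 1 more probe lay 1588 bp beyond the end of the region. That probe, 19421984 to 19422043, had a log2 ratio of 2.08 ± 0.32 (SD, n = 2), against 2.05 for the mean of the other 11. Over the 12 probes and 4 arrays the log2 ratios ran from 1.2 to 2.67. Binding cannot be told apart here from extra DNA copies of the stretch in the UPB1-GFP line. The nearest probe on the left, 21906 bp away, had a log2 ratio of 0.22 ± 0.14 (SD, n = 2). The nearest on the right, 22253 bp away, had -0.32 ± 1.37 (SD, n = 2).

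**Figure D1:**
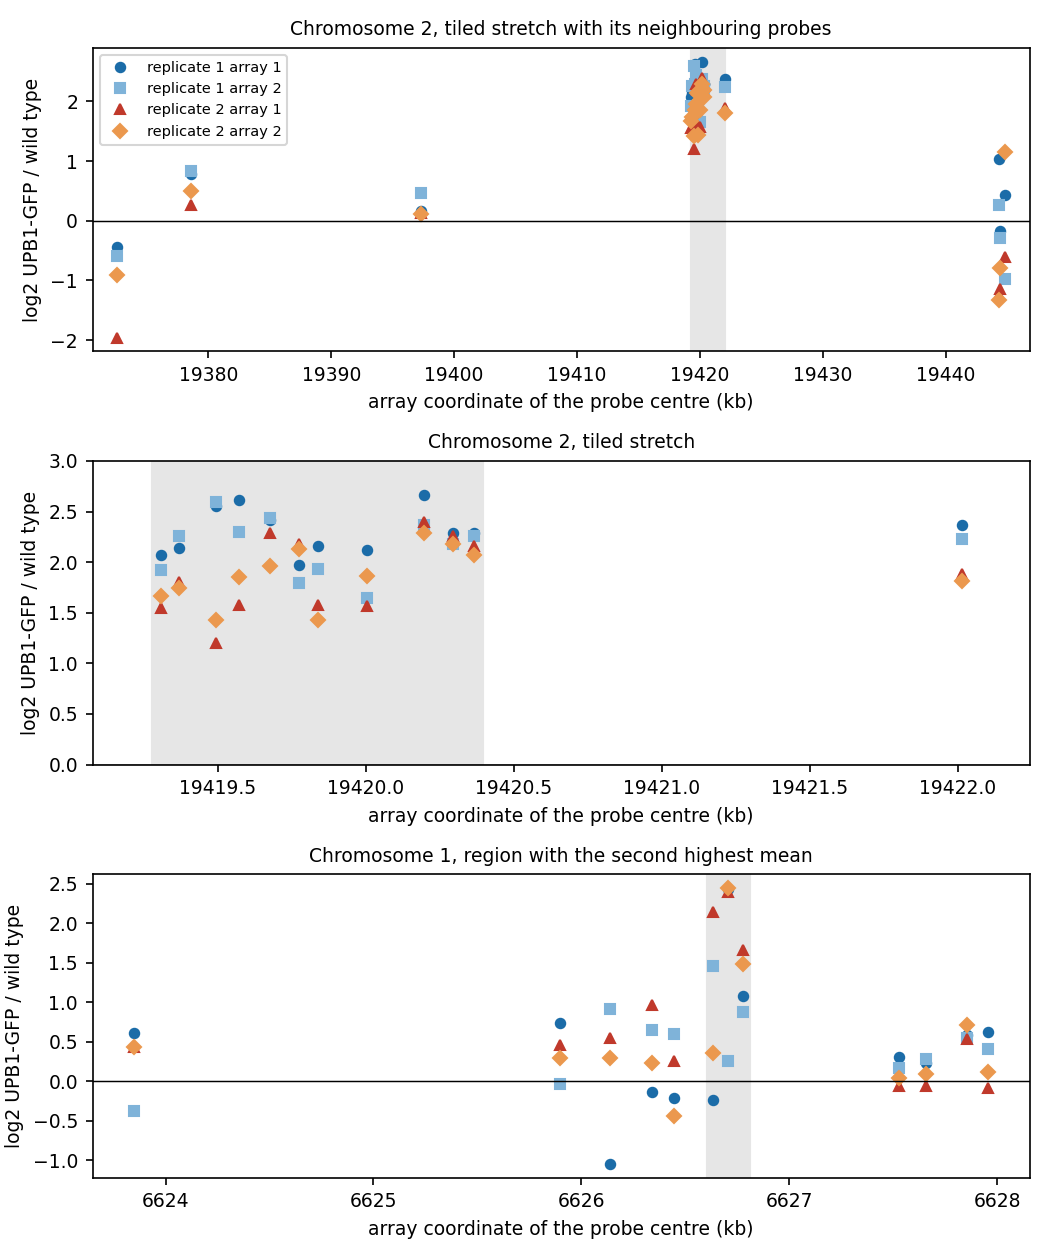
Log2 ratios of UPB1-GFP over wild type (y axis) of each probe on each of the 4 arrays (points) against the array coordinate in kb (x axis), with the called range in grey. Top and middle panels show chromosome 2 at low and high magnification, with the 12-probe stretch in grey at the top and the region 19419278 to 19420395 in grey in the middle, where all values lie between 1.2 and 2.67; the bottom panel shows the region of chromosome 1 from 6626602 to 6626809, where arrays differ more.

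The rule found 3 further regions, each of 3 probes with 2 of them well above background on all arrays. The region on chromosome 1 from 6626602 to 6626809 had a mean log2 ratio of 1.36 ± 0.54 (SD, n = 2), with 0.98 in replicate 1 and 1.75 in replicate 2. The region on chromosome 5 from 16540779 to 16541001 had 1.25 ± 0.25 (SD, n = 2). The region on chromosome 4 from 2717575 to 2717876 had 1.16 ± 0.57 (SD, n = 2). All 4 regions were above 0 on all 4 arrays, which the rule for regions already favours. The mirrored rule gave 0 regions low in both replicates, 0 high in replicate 1 and low in replicate 2, and 1 low in replicate 1 and high in replicate 2. Each replicate alone gave more regions in both directions, 63 high and 37 low in replicate 1 and 103 high and 79 low in replicate 2. At 4 robust SDs, or with all 4 arrays required to pass, 1 region was left, and normexp on the mean signals also gave 1. With normexp the mean log2 ratio of the region on chromosome 2 was 1.65. Those on chromosomes 1, 5 and 4 had 0.22, 0.14 and 0.23. With only bright probes the region on chromosome 2 had 2.06, and those on chromosomes 1, 5 and 4 had 1.59, 1.02 and 2.15. Each of the latter 3 values is a mean of 2 probes. The dim probe left out lay below the mean of the bright ones on chromosomes 1 and 4 and above it on chromosome 5. With only bright probes the rule gave 3 regions high in both replicates and 1 high in replicate 1 and low in replicate 2. With all tested probes but without array 1 of replicate 1, the count of regions high in both replicates was 2. Without array 2 of replicate 1 it was 1, with 1 region low in both replicates.

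At 2 robust SDs, 46 regions were high in both replicates. They lay on all 5 chromosomes, with 15 on chromosome 1, 6 on chromosome 2, 8 on chromosome 3, 7 on chromosome 4 and 10 on chromosome 5. Their mean log2 ratios ran from 0.67 to 2.05, and their median length was 305.5 bp. Of the 46, 45 were above 0 on all 4 arrays, which the rule for regions already favours. In 21 of them all probes were well above background on all arrays. Among these was the region on chromosome 3 from 17578193 to 17578497, with 4 probes and a log2 ratio of 1.45 ± 0.57 (SD, n = 2). Another was the region on chromosome 4 from 8486309 to 8486672, with 4 probes and 1.37 ± 0.05 (SD, n = 2). Both were picked from the 46 after their values were seen. At the same threshold, 11 regions were low in both replicates, 19 were high in replicate 1 and low in replicate 2, and 13 were low in replicate 1 and high in replicate 2. With only probes well above background, the counts were 40 high in both, 12 low in both, 20 and 11. Over the regions of these 4 kinds in all tested probes, the association between the signs of the replicates did not pass 0.05 (odds ratio 2.03, 95% interval 0.691 to 5.95, two-sided Fisher's exact p = 0.206).

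**Figure D2:**
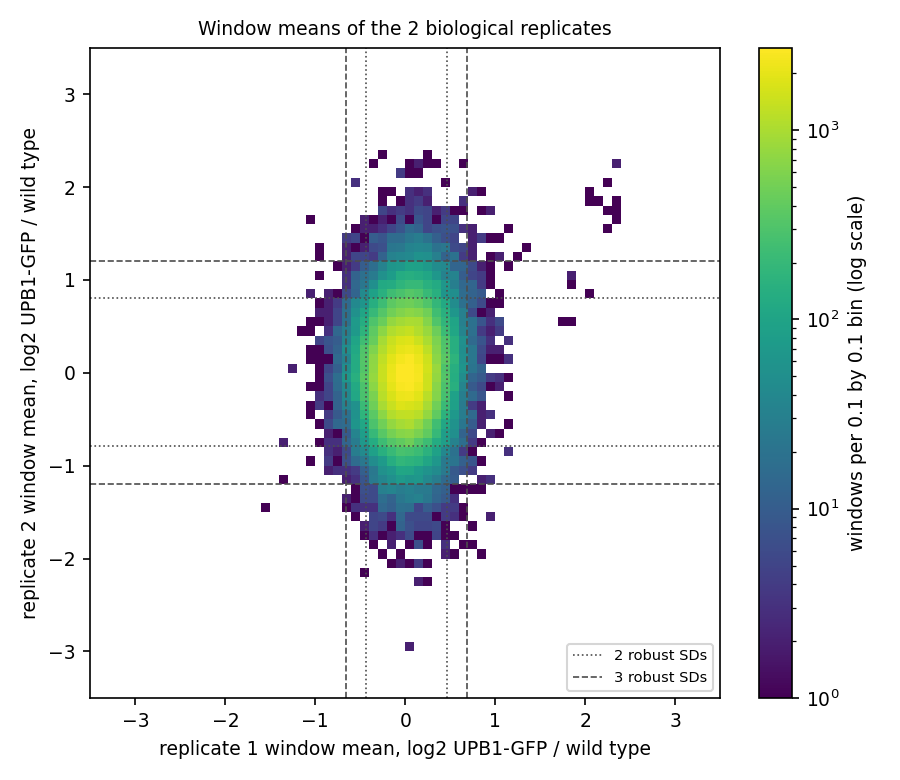
Mean log2 ratio of UPB1-GFP over wild type in windows of 250 bp to each side of a probe in replicate 1 (x axis) and replicate 2 (y axis), with colour for the number of windows per bin on a log scale and lines at 2 and 3 robust SDs on both sides of the median. Windows of the region on chromosome 2 with replicate means of 2.23 and 1.87 stand apart at the upper right, and the bulk of the windows shows no slope.

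Of 39220 intervals of 1200 bp, limma called 3 higher in UPB1-GFP and 0 lower, with 1471 higher and 975 lower at an unadjusted p under 0.05. Chance alone would put a share of 0.05 of all tested intervals, over both directions, under that level, so most of these are no evidence of enrichment. A pair of the called intervals covered the region on chromosome 2 described above. The interval from 19419601 to 19420800, with 7 probes, had a log2 ratio of 2.1 ± 0.11 (SD, n = 2; limma adjusted p = 7.12e-07), higher on 4 of 4 arrays. The interval from 19418401 to 19419600, with 4 probes, had 1.96 ± 0.50 (SD, n = 2; limma adjusted p = 6.43e-06), higher on 4 of 4 arrays. The other called interval lay on chromosome 2 from 13665601 to 13666800. It held 3 probes, 2 of them well above background on all arrays, and had a log2 ratio of 1.15 ± 0.01 (SD, n = 2; limma adjusted p = 0.0157), higher on 4 of 4 arrays. Its call ended with loess, where the log2 ratio was 1.12, with GC and brightness trends removed (1.09), with a random block over 4 arrays (1.15), with the deposited sign (0.01) and with normexp (0.03). With a variance trend over the number of probes, an added alternative, these 3 intervals were called and so was 1 more, on chromosome 3 from 17577601 to 17578800. That interval held 10 probes and had a log2 ratio of 1.01 ± 0.59 (SD, n = 2; limma adjusted p = 0.00514 with the trend and 0.16 without it). It contains the region on chromosome 3 named above. No lower interval passed the threshold. The lowest of those below 0 on all 4 arrays was on chromosome 3 from 9370801 to 9372000, with a log2 ratio of -0.99 ± 1.00 (SD, n = 2; limma adjusted p = 0.307) and 1 of 3 probes well above background. The next 4 of that kind started at 22131601 and 9463201 on chromosome 3, at 19561201 on chromosome 1 and at 14790001 on chromosome 4. Their log2 ratios were -0.89 ± 0.02, -0.82 ± 0.76, -0.83 ± 0.54 and -0.81 ± 0.85 (SD, n = 2 each). Only 2 of 3 probes in the interval from 9463201 and 2 of 4 in that from 14790001 were well above background. The small SD of the interval from 22131601 hides a difference within replicate 1, whose arrays gave -1.67 and -0.07. Its log2 ratio was -0.49 without array 1 of replicate 1 and -1.29 without array 2 (limma adjusted p = 0.00735). With normexp the log2 ratios of these 5 low intervals lay between -0.37 and -0.19, and in replicate 1 alone the intervals from 9370801, 9463201, 19561201 and 14790001 had -0.28, -0.28, -0.45 and -0.21. Without array 1 of replicate 1, 32 intervals were called higher and 7 lower, and without array 2 of replicate 1, 4 were called higher and 4 lower. With intervals of 500 bp 69 were called higher and 16 lower, centring on the mode gave 10 higher, normexp gave 6 higher, and the fit with a robust variance trend over the mean ratio called 0, with the log2 ratios of the 3 intervals unchanged. The mean ratio is itself the tested value, so that last fit cannot show whether the calls hold.

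Over all tested intervals, 4930 (12.6%) were above 0 on all 4 arrays and 4533 (11.6%) were below 0 on all 4. The shares with both arrays of a replicate above 0 were 29% in replicate 1 and 41.4% in replicate 2, and those with both below 0 were 25.1% and 42.5%. Replicates independent of each other would then give 12% above 0 on all 4 arrays and 10.7% below.

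Of 233430 single probes, limma called 6 higher and 1 lower, with 8399 higher and 6276 lower at an unadjusted p under 0.05. Chance alone would put a share of 0.05 of all tested probes, over both directions, under that level. Of the 6, 4 belonged to the region on chromosome 2. Besides the probe at 19420169, these started at 19419647, with a log2 ratio of 2.28 ± 0.21, at 19420264, with 2.23 ± 0.01, and at 19420336, with 2.19 ± 0.11 (SD, n = 2 each). The remaining 2 were dim. The probe on chromosome 1 from 11801294 to 11801353 was well above background in the wild type channel on only 2 of 4 arrays, and the probe on chromosome 5 from 8359491 to 8359550 on none, so only bounds are given for their folds. On the mean over the arrays, their DNA was at least 6.65-fold and at least 6.31-fold higher in UPB1-GFP. These bounds used channel values after loess and Aquantile, with the wild type set to the lowest signal well above background where it was dimmer. They do not hold for each array. The median-centred log2 ratio of the chromosome 1 probe was 1.22 on array 1 of replicate 1. That of the chromosome 5 probe was 2.13 in replicate 1 and 3.45 in replicate 2. The latter probe lay in a region at 2 robust SDs whose 5 probes, 1 of them well above background, had a mean of 0.75. Their limma adjusted p of 0.0251 comes from the median-centred ratios and not from these channel values, and with loess within arrays 0 probes were called. The lower probe was on chromosome 1 from 17238275 to 17238334, with -2.51 ± 0.85 (SD, n = 2; limma adjusted p = 0.0386), lower on 4 of 4 arrays. These single-probe counts rested on the setting. With bright probes only, with loess, with the value table in the direction of the labels, or without array 2 of replicate 1, array 1 of replicate 2 or array 2 of replicate 2, 0 probes were called, and without array 1 of replicate 1 only 1 was. Normexp called 41 higher and 17 lower, and centring on the mode called 10 higher and 1 lower.

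No excess of CANNTG E-boxes in the regions was detectable, given how few regions there were. The sequence CANNTG was in the probes of 2 of the 4 regions (50%) and of 201 of 400 control stretches (50.2%; odds ratio 0.99, 95% interval 0.0712 to 13.8, two-sided Fisher's exact p = 1). CACGTG, the G-box, was in 0 of the 4 regions and in 8 of 400 control stretches (two-sided Fisher's exact p = 1). Over the 46 regions at 2 robust SDs, CANNTG was in 21 (45.7%) against 2038 of 4600 control stretches (44.3%; odds ratio 1.06, 95% interval 0.56 to 1.97, two-sided Fisher's exact p = 0.882). CACGTG was in 3 of the 46 (6.52%) against 72 of 4600 (1.57%; odds ratio 4.38, 95% interval 0.851 to 14.2, two-sided Fisher's exact p = 0.0374, and 0.224 after Benjamini-Hochberg adjustment over the 6 tests of motifs and thresholds). The probes cover only part of each region, so an E-box between probes was not counted. The region on chromosome 2 from 19419278 had CANNTG in 2 of its 11 probes and CACGTG in 0.

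The dye swaps agreed very differently in the replicates. Across probes, which are not independent replicates, the log2 ratios of the dye swap arrays correlated with Pearson's r = 0.815 (Spearman's rho = 0.803) in replicate 2 and with r = 0.0236 (rho = 0.0208) in replicate 1. With only probes well above background on all arrays, r was 0.901 in replicate 2 and 0.238 in replicate 1. In replicate 1, r rose from -0.15 in the dimmest of 10 equal groups of probes to 0.391 in the brightest. The means of the replicates correlated with r = 0.0464 (rho = 0.0454) over all probes and 0.0454 over bright probes. Over intervals, r was 0.858 within replicate 2, 0.0894 within replicate 1 and 0.0566 between the replicates. With normexp on the mean signals, r within replicate 1 fell to -0.792 and r between the replicates to -0.125.

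**Figure D3:**
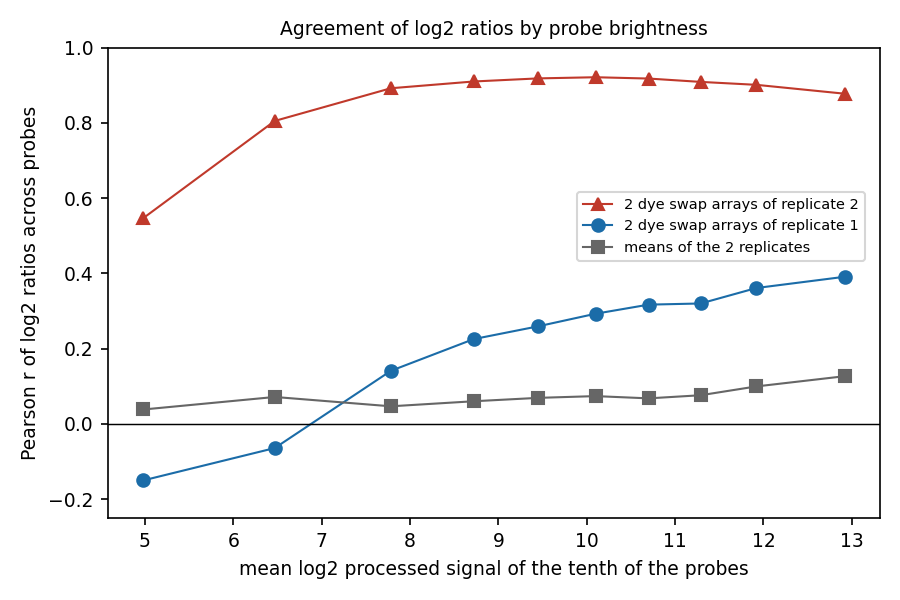
Pearson's r of log2 ratios across probes (y axis) in 10 equal groups of probes ordered by brightness, placed at their mean log2 processed signal (x axis), for the dye swap arrays of replicate 2 (triangles), those of replicate 1 (circles) and the means of the replicates (squares). Replicate 2 reaches r = 0.922, replicate 1 rises from -0.15 to 0.391, and r between the replicates stays at or below 0.127.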

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

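The comparison of the 4 arrays was made for the 19 regions, intervals and probes named or called in the results. With 4 independent arrays, chance alone would single out about 1 in 20 such sets. The arrays are 2 dye swap pairs, and many items were selected for agreement between replicates, so this rate need not hold. Where the replicates differ, the values fall in pairs, which can hide a single array standing apart. The only item past the limit was the probe on chromosome 1 from 11801294 to 11801353. The log2 ratio of its processed signals was 1.22 on array 1 of replicate 1 and 3.19 to 3.36 on the other 3 arrays, so that the gap was 0.92 of the whole range. Its wild type channel was well above background on only 2 of the 4 arrays, so some of these ratios are not measured differences and the gap cannot be read as one. No explanation was tested for this probe.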

How the results depend on the processing

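In the dimmest of 10 groups of probes the arrays of replicate 1 had r = -0.15, and with n = 2 a test without either replicate is not possible, so only values were taken then. Without 1 array, intervals called higher ran from 3 to 32 and lower from 0 to 7, probes called higher from 0 to 1 and lower from 0 to 0, and regions from 1 to 4. The extremes were 32 and 7 intervals without array 1 of replicate 1, and 1 region without array 2 of replicate 1. Regions numbered 103 without replicate 1 and 63 without replicate 2. Those 2 counts follow a looser rule, since only the remaining replicate had to pass. The region on chromosome 2 from 19419278 kept a log2 ratio of 1.87 to 2.23 in these runs. Alternatives chosen after the data were seen are other interval lengths, the deposited sign, removed GC and brightness trends, the variance trend over probe number, the trend over the mean ratio and the robust fit taken singly, and 4 arrays with a random block. The causes of the changes below were not tested unless stated. Normexp gave 6 intervals higher, 41 probes higher, 17 probes lower, 1 region, and r of -0.792 within replicate 1, 0.852 within replicate 2 and -0.125 between them. Loess gave 0 probes in either direction and r of 0.169, 0.835 and 0.0547 in the same order. Bright probes only gave 0 probes in either direction, r of 0.238 and 0.901 within the replicates, and r of 0.0454 between them. Removed trends gave 0 probes in either direction and r of 0.161, 0.83 and 0.0734. Centring on the mode gave 10 intervals and 10 probes higher. The value table turned to the labels' direction and the random block each gave 0 probes in either direction. A robust variance trend over the mean ratio gave 0 probes and 0 intervals and ended the calls of all 3 intervals (adjusted p 0.906 to 0.939), whose log2 ratios stayed at 1.15, 1.96 and 2.1, so only the variance model differed. The trend alone did the same (0 probes, 0 intervals, adjusted p 0.942 to 0.999), while the robust fit alone kept 3 intervals and called 2 probes higher and 0 lower. In both fits with this trend the mean ratio is also the tested value, so the prior variance depends on the size of the effect. Calls lost there cannot show whether the intervals hold. The interval on chromosome 2 from 13665601 also lost its call with loess, removed trends and the random block, where its log2 ratio stayed at 1.12, 1.09 and 1.15 (adjusted p 0.292, 0.226 and 0.166), and with normexp and the deposited sign, where it fell to 0.03 and 0.01 (adjusted p 1 for both). The deposited sign also ended the calls of the intervals from 19418401 and 19419601, at 0.36 and 0.08. Intervals of 500 bp gave 69 higher and 16 lower. Regions numbered 46 at 2 robust SDs, 1 at 4 and 1 with all 4 arrays required. The share of regions with CANNTG was 45.7% at 2 robust SDs and 100% of 1 region at 4, both above their control stretches, against 50% just below them at 3. The deposited sign of the value table, which turns replicate 2, gave 0 intervals and 0 probes in either direction, and 0 regions high and 2 low in both replicates. By construction it turned the regions at 6626602, 16540779 and 2717575 to -0.357, -0.175 and -0.401, and the low intervals at 19561201, 22131601, 9370801, 9463201 and 14790001 to 0.388, 0.0199, 0.667, 0.541 and 0.606. Not run were promoters with their windows, gene lists and the peroxidase list, for want of a build, and 4 arrays with a dye coefficient and a random block, which could not be fitted.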

Other observations

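The tests of GC and brightness trends, of shifted replicates and of E-boxes were written down before their results were seen, and the other tests here were chosen afterwards.

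Of the 12 probes in the stretch from 19419278 to 19422043, 8 were spotted more than once, against 0.168% of all probes. The largest groups of such probes elsewhere were near 0 in both replicates. The 32 on chromosome 4 from 9883997 to 9888996 had log2 ratios of -0.08 and 0.01, and the 19 on chromosome 3 from 20697820 to 20700816 had 0.00 and -0.08.

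Neighbouring probes within a replicate carried similar ratios over short distances. For probe pairs under 100 bp apart, r was 0.425 in replicate 1 and 0.587 in replicate 2. At 300 to 400 bp it was 0.113 and 0.0403. At 1500 to 2000 bp it was 0.0489 in replicate 1 and 0.00754 in replicate 2. Pairs set across the replicates had r of 0.0144 under 100 bp. Probe pairs are not independent replicates.

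The enrichment of the stretch on chromosome 2 was flat. A single focal site of binding is argued against by the probe 1588 bp beyond the region, whose log2 ratio exceeded the mean of the other 11 by 0.0265, against an SD of 0.216 between those probes. Dim spots are argued against, since 12 of its 12 probes were well above background in both channels on all arrays. A candidate explanation is that the UPB1-GFP line holds extra DNA copies of this stretch, as a transgene made from genomic sequence would bring. The SD between its probes was 0.24 in replicate 1 and 0.32 in replicate 2. In 634 runs of 12 neighbouring, equally bright probes elsewhere, the median SD was 0.216 and 0.419, and the 95% limit was 0.334 and 0.658. Enrichment of every probe alike would give such SDs, but so would even binding, so these values do not favour extra copies over binding. UPB1 itself lies on chromosome 2, but whether this stretch is its locus was not settled here, and binding at several sites of the stretch stays open.

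The replicates shared little of their ratio pattern. Labelling and hybridisation noise alone is argued against in replicate 2, whose dye swap arrays correlated at 0.815. In replicate 1 the value over all probes was 0.0236. Between arrays of different replicates, r was -0.0239 and -0.00867 for pairs of opposite dye and 0.00591 and 0.148 for pairs of the same dye. A dye effect would lower r in a dye swap and raise it between arrays of the same dye. The comparison therefore leaves both noise and a dye effect open over all probes of replicate 1. In the 2 dimmest of 10 equal groups by brightness, however, r within replicate 1 was -0.15 and -0.06. Noise alone would give r near 0, so these values argue against noise alone for those dim probes. Over probes well above background r was 0.238 in replicate 1, against at most 0.103 between arrays of different replicates, which argues against noise alone for those probes. The GC content trend ran in opposite directions in the replicates (r 0.0636 and -0.143), and so did the brightness trend over most probes. From the third to the ninth of 10 equal groups by brightness, the mean log2 ratio rose from -0.086 to 0.0635 in replicate 1 and fell from 0.111 to -0.125 in replicate 2, although r with brightness over all probes was -0.0202 and -0.141. With both trends removed r between the replicates was only 0.0734. A turned replicate 2, as in the value table, is argued against by 0 regions high in both replicates with that sign (and 2 low), against 4 high (and 0 low) with the labels' dyes. A difference between the biological samples or their amplification may remain, and was not tested, since replicate and scan date coincide.

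At 2 robust SDs, more regions were high in both replicates than in any other combination of signs. Coincidence of fluctuations at unrelated places is argued against, because 0 of 1000 shifts of replicate 2 along the probes gave as many (46, against at most 12; permutation p = 0.001, the smallest they can give). The shifts also fell short of the 19 and 13 regions of opposite sign, so they understate what places of high variance in both replicates could give. For such places, with no shared direction, the odds ratio of the signs was 2.03 (95% interval 0.691 to 5.95), which leaves them open, since the regions are too few. Binding at E-boxes stays open too, with an odds ratio of 1.06 (95% interval 0.56 to 1.97) for CANNTG against control stretches.

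The Agilent control spots were of 9 kinds. The bright kind AtPC, 480 spots per array, had median log2 ratios of -0.18 and -0.15 on the arrays of replicate 1 and -0.12 and -0.16 on those of replicate 2. Other bright kinds did not keep 1 sign over the arrays. In the same order, LACC (2944 spots) had 0.10, 0.13, -0.08 and -0.26, and DCP (300 spots) had 0.04, -0.03, -0.28 and -0.24. AtCGHBrightCorner (14 spots) had 0.08, -0.01, 0.40 and -0.07. In dim kinds the dye swap arrays of each replicate had opposite signs. The medians were above 0 where UPB1-GFP was in Cy5 and below 0 where it was in Cy3, as a dye effect would give. The medians were -0.22 and 0.65, then 0.24 and -0.45, for NC2 (564 spots), and -0.35 and 0.79, then 0.28 and -0.45, for DarkCorner (35 spots).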
